A study of Bos taurus with 5 samples.

How the data were processed

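RNA sequencing values of 5 cattle libraries, labelled brain, skin, lung, heart and limb, were analysed, with 1 library per label and no replicates. Per the labels' protocols, cells were lysed, their RNA was pre-amplified and libraries were prepared on a microfluidic chip that handles single cells. Per the submitters' processing notes, bcl2fastq, STAR (read alignment) and RSEM (estimation of expression) were used with the ARS-UCD1.2 genome build. Their versions, the annotation release and any filters are not given in the sources used here.

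The authors deposited 1 table of 27607 genes by 5 libraries, with Ensembl gene identifiers and, for 19856 of them, gene names, which were used as the table gives them. The deposited values were taken as FPKM (fragments per kilobase of a transcript, scaled to the total of mapped fragments) by elimination, since neither the table nor the labels name the unit. Between 98.7% and 99.1% of the values above 0 were not whole numbers, which argues against counts, although estimated counts need not be whole. Each library summed to between 1072430 and 1172800, more than the fixed total of TPM. A table of gene names for a later assembly was checked, and 0 of the identifiers matched it, so no coordinates are given. Of the names, 1969 occurred more than once, and each gene was kept as a separate entry. Small RNAs and members of gene families can share reads with near-identical copies, so their values are uncertain.

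With no counts, the values were used as deposited, with no count model, no standard error and no p-value. A gene was called enriched in a library at 10 FPKM or more with (FPKM + 1) at least 4 times the highest (FPKM + 1) of the other 4. It was called depleted when the lowest of the other 4 was at least 10 FPKM and 4 times its own value on the same scale. Adding 1 understates the ratio of low genes, and no ratio is given against a library at 0. For the 10 pairs of libraries, genes with the higher value at 10 FPKM or more and a ratio of at least 4 after adding 1 were counted, and Pearson and Spearman correlations of log2(FPKM + 1) were computed across the 8694 genes with a mean of at least 1 FPKM. Detection was counted at 1 FPKM or more.

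The text names, for each library, the 15 enriched genes with a gene name and the largest ratio (in part, with the rest summarised and 1 of them not reported here), the 5 most abundant genes, the 5 depleted genes with a name and the largest ratio, and members of 36 gene lists with the largest and smallest differences. The lists, the rules of size, the rule for named genes and most of the alternatives were chosen before the data were examined. Of the lists, 24 hold markers of cell types and 12 hold processes or positional genes, and 14 of the 24 belong to 1 of the 5 tissues. For a list with at least 3 members at a mean of 1 FPKM or more, each member's log2(FPKM + 1) in a library minus its mean in the other 4 was taken. The median over members was set against 10000 random lists drawn from 20 bins of mean level with a fixed seed, and a list was said to stand apart outside the central 95%. This percentile describes the libraries and is not a p-value.

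Depth was read from the low values, where a gene's values in 2 libraries stand in ratios of small whole numbers once the libraries' depths are divided out. Ratios of whole numbers up to 4 within 0.3% were counted for genes between 2 and 200 FPKM. Between the brain- and heart-labelled libraries 273 of 3554 genes lay on such ratios at the best offset, against a median of 59 and at most 170 at other offsets. In a joint fit of all 5 libraries, 1263 ratios summed over the 10 pairs lay on whole-number ratios, against 1174 and 1183 with the heart-labelled depth changed by a factor of 2. For the skin-, lung- and limb-labelled libraries an offset differing by a factor of 2 in at least 1 direction explained nearly as many ratios, so their depth is not stated. With the worth of 1 read at 0.5 and 2 times the fit, 1236 and 1218 ratios remained for the skin label. The lung label had 1258 and 1157 and the limb label 1246 and 1179, so there only the first came close. No counts could be recovered, so thinning to equal depth was not run and no counting interval is given.

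The alternatives were other minimums, pseudocounts and ratios, the mean of the other libraries as reference, each other library left out of the reference, rescaling by the median ratio and by a trimmed mean of log ratios, and a total without mitochondrial and haemoglobin genes. A minimum of 200 FPKM, genes other than small RNAs and the median as list reference were added after seeing the data. The heart-labelled library had the largest shift between libraries under rescaling, -0.14 on the log2 scale by the median ratio and -0.13 by the trimmed mean. The rules were tested on simulated data in which 100 genes were raised 8-fold and 100 were raised 2-fold in the heart-labelled library. All 100 of the first and 0 of the second were called enriched there, and 0 genes were called in the other libraries. The simulated values carried only small noise around the mean profile and no counting error of few reads. The result therefore shows that the rule works as written and gives no rate of false calls in these libraries. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.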

Results

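Gene expression was measured in 5 RNA sequencing libraries from cattle (Bos taurus), 1 for each of the tissue labels brain, skin, lung, heart and limb. The labels' protocols describe cells that were lysed and pre-amplified on a microfluidic chip made for single cells. How many cells or animals stand behind a library is not given in the sources used here. With 1 library per label there were no replicates, so every difference below describes these libraries only and carries no error or p-value.

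The table held 27607 genes, of which 19856 had a name, with values taken as FPKM. Of these genes, 9877 were above 0 in at least 1 library and 2607 were above 0 in all 5. Genes at 1 FPKM or more numbered 6318 in the brain-labelled library, 4868 in the skin-labelled, 5707 in the lung-labelled, 6394 in the heart-labelled and 5075 in the limb-labelled library. The median of the values above 0 lay between 21.4 FPKM in the heart-labelled and 38.7 FPKM in the skin-labelled library. Read totals were not analysed here, so depth is known only from the spacing of low values. By the best fit of that measure the heart-labelled library had 81.1% of the depth of the brain-labelled library. In the brain-labelled library 1 read was worth a median of 7.20 FPKM among the 273 genes on the spacing. This level is rough, since between 2 and 200 FPKM, where it was sought, a median of 59 genes lay on the spacing at other offsets by chance. Up to 170 lay on it at single offsets, which can include ones near other small whole-number ratios. The level can also be too high, since 2 reads against 2 were counted as 1 against 1. For the skin-, lung- and limb-labelled libraries the depth was known only up to a factor of 2. A gene listed at 0 can therefore be expressed below the level that these libraries could show, and genes used by nearly every cell, such as UQCRC2 of the respiratory chain in the limb-labelled library, were also listed at 0.

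What the 5 libraries had in common was examined through their most abundant genes. TMSB10 and TMSB4X, which encode small proteins that bind actin monomers, stood at 18325 to 43905 FPKM and 12611 to 34719 FPKM. S100A2, a calcium-binding protein, ranged from 12505 to 23575 FPKM, ACTB (beta-actin) from 7610 to 16627 FPKM and MYL6 (a myosin light chain) from 10460 to 18397 FPKM. The lists of the 5 most abundant genes of each library held only 8 different genes. TMSB10 and the unnamed gene ENSBTAG00000043567, at 16162 to 23769 FPKM, were in all 5 of these lists. COX3, a mitochondrially encoded subunit of cytochrome c oxidase, ranged from 11027 to 19897 FPKM. An exception was the unnamed gene ENSBTAG00000043545, at 27164 FPKM in the skin-labelled and 21909 FPKM in the lung-labelled library and listed at 0 in the other 3. Among the 50 most abundant genes of each library, 27 were shared by all 5. The 10 most abundant genes took at most 18.3% of the summed FPKM, in the heart-labelled library, mitochondrially encoded genes with a name 4.27% to 6.09%, and ribosomal protein genes 11.0% to 14.8%.

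Whether each library carried the markers of the tissue on its label was asked next, with gene lists for 14 cell types or regulator groups of the 5 tissues. Neuronal genes such as SNAP25, SYT1 and STMN2 were listed at 0 in all 5 libraries, and the brain-labelled library had 0 of the 22 entries of the neuron list above 0. MAP2, a neuronal microtubule protein, was listed in the other 4 libraries at 4.13 to 13.2 FPKM, and GAD2, an enzyme of GABA synthesis, only in the lung-labelled library at 10.4 FPKM. In the skin-labelled library 2 of 18 keratinocyte entries were above 0, PERP (a desmosome-associated membrane protein) at 204 FPKM and KRT10 at 20.8 FPKM, and both were also above 0 in the lung-, heart- and limb-labelled libraries. KRT5, the keratin of basal epidermis, was listed at 51.0 FPKM in the lung-labelled library and at 0 in the other 4. In the lung-labelled library only PDPN, at 4.5 FPKM, was above 0 among 16 alveolar entries, while the surfactant gene SFTPC was listed only in the limb-labelled library, at 34.2 FPKM. The heart-labelled library had 2 of 24 cardiomyocyte entries above 0, ACTC1 (cardiac actin) at 5.21 FPKM and the fatty acid carrier FABP3 at 36.0 FPKM. ACTC1 was higher in the brain-labelled library, at 57.7 FPKM, and in the limb-labelled library, at 231 FPKM, and FABP3 was higher in the skin-labelled library, at 324 FPKM, and in the lung-labelled library, at 246 FPKM. The limb-labelled library had 2 of 25 skeletal muscle entries above 0, the skeletal actin ACTA1 at 37.6 FPKM and the slow troponin TNNT1 at 18.1 FPKM, while MYOD1, MYOG and CKM were listed at 0. Over the 5 main lists, 7 of 105 entries were above 0 in the library with the matching label. Because these markers did not match the labels, each library is named below by its label only, and a direction drawn for a label is not taken as one for that tissue.

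The remaining tissue lists were counted in the same way. In none of the 14 lists did the library with the matching label have more entries above 0 than each of the other 4. Of the 17 neural progenitor and astrocyte entries, 5 were above 0 in the brain-, skin- and heart-labelled libraries, 4 in the lung-labelled and 3 in the limb-labelled library. They included PAX6, a regulator of eye and forebrain development, at 16.7 to 42.6 FPKM, the lipid-binding protein FABP7 at 70.5 to 151 FPKM and the intermediate filament NES at 6.64 to 119.7 FPKM, all above 0 in all 5 libraries. Oligodendrocyte genes had at most 2 of 12 entries above 0, in the lung-labelled library (CNP at 96.2 FPKM and MOG at 7.34 FPKM). Hair follicle genes were above 0 only through MSX2 in the brain-labelled library, at 33.4 FPKM, and melanocyte genes only through SLC45A2 in the limb-labelled library, at 0.58 FPKM. Airway genes were above 0 for 3 of 9 entries in the limb-labelled and 1 of 9 in the lung-labelled library, the lung mesenchyme regulators for 0 of 8 in each library, and tendon genes for 2 of 5 in the heart-labelled and 0 of 5 in the limb-labelled library. In the limb-labelled library 3 of 24 cartilage and bone entries were above 0, led by SPP1 (osteopontin) at 1753 FPKM. SPP1 stood at 886 FPKM in the heart-labelled, 93.1 FPKM in the lung-labelled and 39.7 FPKM in the brain-labelled library. Limb patterning genes were above 0 for 1 or 2 of 24 entries in each library. PRRX1, a regulator of limb mesenchyme, was at 282 FPKM in the skin-labelled, 199 FPKM in the heart-labelled and 22.8 FPKM in the limb-labelled library. All 39 entries of HOX genes, which mark position along the body axis, were listed at 0 in all 5 libraries.

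**Figure D1:**
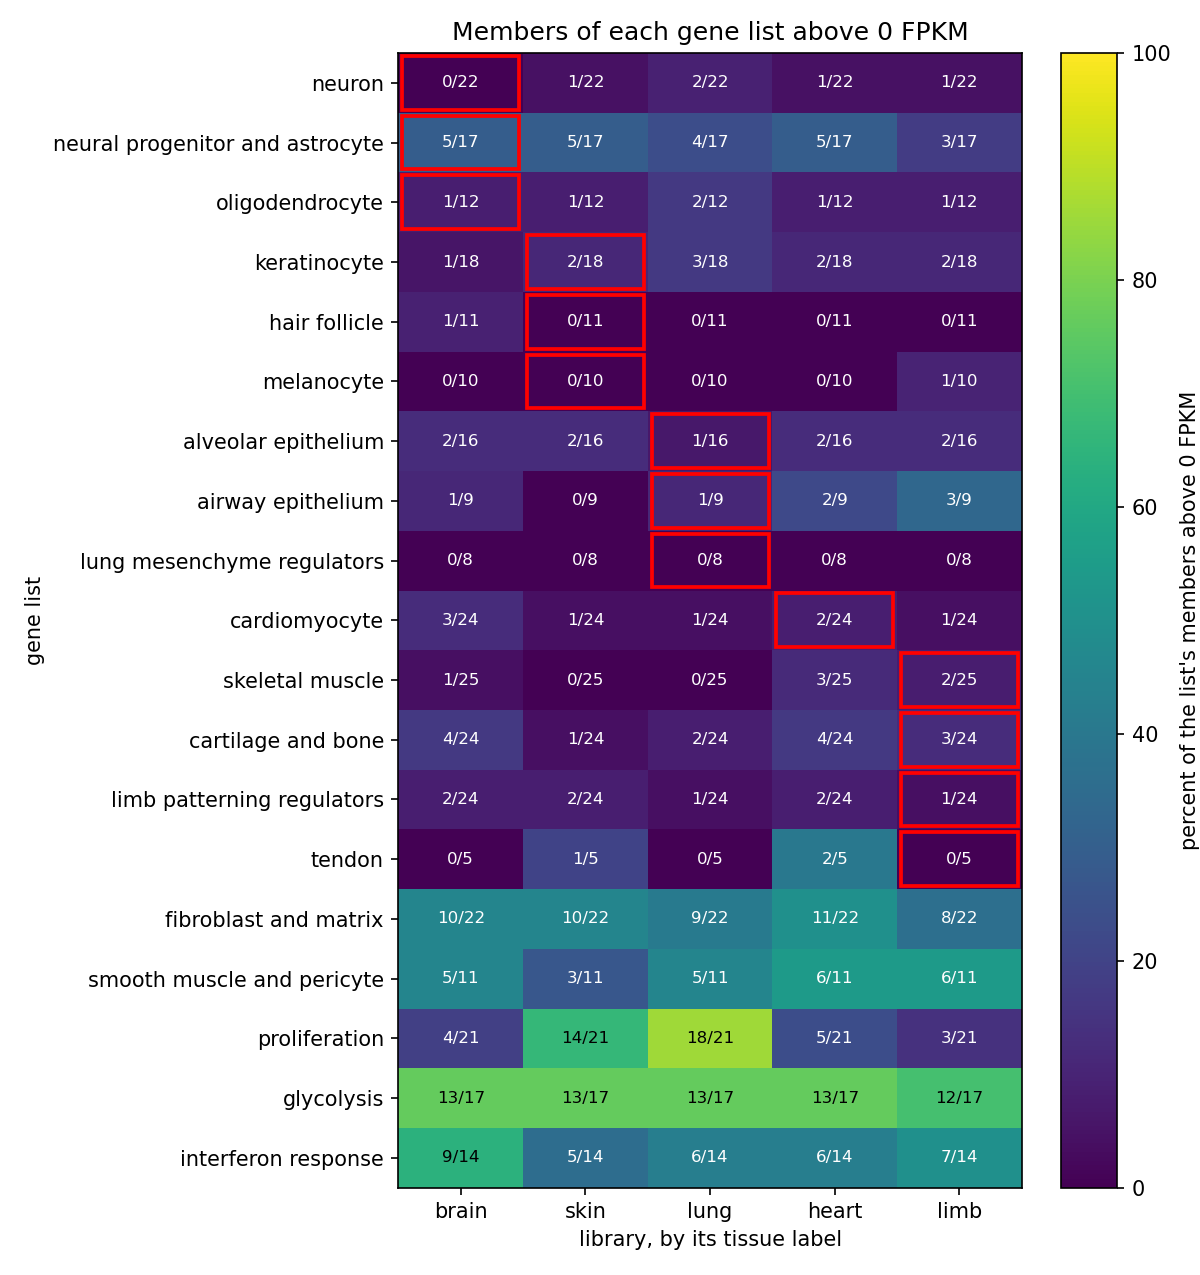
Number of members of each gene list above 0 FPKM in each library, written as members above 0 over members in the table, with the colour giving the percentage. Red frames mark the library whose label matches the list, where at most 5 of 17 members were above 0, against 18 of 21 proliferation genes in the lung-labelled library.

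Fibroblast and matrix genes had 8 to 11 of 22 entries above 0 in each library and smooth muscle and pericyte genes 3 to 6 of 11. In at least 1 library 13 of the 22 and 6 of the 11 were above 0. DCN, LUM, PDGFRB and THY1 of the first list and MYH11, RGS5 and MCAM of the second were listed at 0 in all 5 libraries. These counts therefore do not name a cell type. Markers of blood, fat, vessel and nerve sheath cells were scarce. Macrophage and microglia (12 entries), lymphocyte (10) and adipocyte (7) genes were listed at 0 in every library. Endothelial genes were above 0 only through FLT1, a receptor of vascular growth factors, at 15.8 FPKM in the brain-labelled and 34.8 FPKM in the lung-labelled library. Erythroid genes were above 0 only through the globin HBA, at 59.5 FPKM in the lung-labelled library. Of 13 general epithelial entries, SPINT2 (a membrane-bound protease inhibitor) was above 0 in all 5 libraries, at 50.2 to 145 FPKM, and CDH1 (E-cadherin) in the skin-labelled, lung-labelled and heart-labelled libraries, at 55.7, 14.1 and 13.8 FPKM. The mesothelial gene MSLN ranged from 1.21 FPKM in the skin-labelled to 73.5 FPKM in the heart-labelled library. Among Schwann cell and neural crest genes, PMP22 was highest in the lung-labelled library, at 105 FPKM, and ERBB3 stood at 1.2 FPKM in the heart-labelled library. XIST, set aside as a check of sex, was not among the gene names of the table.

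Each library was then compared with the other 4 to find genes at 10 FPKM or more and at least 4 times the highest of the others after adding 1. In the brain-labelled library CYP3A4, a drug-metabolising cytochrome, stood at 281 FPKM, the glycolytic aldolase ALDOC at 86.3 FPKM, MCTS1, a factor in translation re-initiation, at 76.0 FPKM and the amino acid transporter SLC43A1 at 74.1 FPKM, each listed at 0 in the other 4. Of the 15 named genes with the largest ratios, 10 were small RNAs, among them bta-mir-3533 at 1057 FPKM and SCARNA13 at 136 FPKM. FPKM is scaled to the length of a transcript, so a few reads on a short RNA can give a high value. The 15 also included the SUMO-directed ubiquitin ligase RNF4. Among genes above 10 FPKM in the other 4 libraries, PERP, listed there at 98.8 to 243 FPKM, MGST1 (a microsomal glutathione transferase) at 66.9 to 654 FPKM, BORCS8 at 49.7 to 118 FPKM, UQCC1 (an assembly factor of respiratory complex III) at 49.4 to 148 FPKM and SEPHS1 at 46.2 to 86.8 FPKM were listed at 0 in the brain-labelled library. In all, 342 genes were enriched in this library, of which 235 (68.7%) were listed at 0 in the other 4, and 53 were depleted. Without the heart-labelled library in the reference the enriched genes numbered 555.

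In the skin-labelled library the cell-surface proteoglycan SDC2 stood at 235 FPKM, the antiproliferative gene BTG2 at 132 FPKM, BAALC at 122 FPKM, the calcitonin-related peptide CALCB at 118 FPKM, the elastase CELA1 at 104 FPKM, the retinol dehydrogenase RDH11 at 77.4 FPKM and the replication factor CDC45 at 79.6 FPKM, all listed at 0 elsewhere. GCDH (lysine breakdown) at 88.5 FPKM, ZBTB6 at 83.0 FPKM, ZDHHC13 at 76.0 FPKM, TSKU at 75.3 FPKM and the cyclin-dependent kinase inhibitor CDKN2D at 73.8 FPKM were also among the 15 named genes, with 1 small RNA. Listed at 0 in this library were the tetraspanin TSPAN3, at 197 to 539 FPKM in the other 4, the ubiquitin-conjugating enzyme UBE2B at 185 to 296 FPKM, asparagine synthetase ASNS at 145 to 632 FPKM, CNPY2 at 128 to 227 FPKM and PIGY at 107 to 187 FPKM. The library had 340 enriched genes, 174 of them (51.2%) listed at 0 in the other 4, and 272 depleted genes. Without the lung-labelled library in the reference there were 517 enriched genes.

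In the lung-labelled library the methyltransferase N6AMT1 was at 162 FPKM, the meiotic recombination factor MND1 at 159 FPKM and the spermine acetyltransferase-like gene SAT2 at 109 FPKM. Several of the 15 named genes act in the cell cycle: GINS2 (replication helicase complex) at 105 FPKM, MIS18A and OIP5 (centromere assembly) at 103 FPKM each, CDKN3 (a phosphatase acting on cyclin-dependent kinases) at 95.6 FPKM and RRM2 (ribonucleotide reductase) at 148 FPKM. RRM2 was listed at 0.45 FPKM in the skin-labelled library, a level near the smallest values in the table, and the others at 0 elsewhere. Another 5 of the 15 were small RNAs. AP1S2 (clathrin adaptor), at 108 to 267 FPKM in the other 4, RND3 at 94.2 to 153 FPKM, GRHPR (glyoxylate reductase) at 86.6 to 212 FPKM, the cap-binding protein EIF4E2 at 73.9 to 144 FPKM and LYRM2 at 72.0 to 103 FPKM were listed at 0. This library had 442 enriched genes, with 245 (55.4%) listed at 0 elsewhere, and 189 depleted genes.

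In the heart-labelled library the Mediator subunit MED28 stood at 146 FPKM, the smooth muscle actin ACTG2 at 136 FPKM, HSPB11 (intraflagellar transport) at 82.4 FPKM, the phosphatase DUSP23 at 69.2 FPKM, RBMS2 at 66.0 FPKM, PIGL at 62.9 FPKM and SPRY2, an inhibitor of growth factor signalling, at 58.7 FPKM. All were listed at 0 in the other 4, and 4 of the 15 named genes were small RNAs. The growth factor midkine (MDK), at 194 to 599 FPKM in the other 4, the immunoproteasome subunit PSMB9 at 123 to 494 FPKM, CCDC25 at 76.7 to 200.1 FPKM, BDH2 at 76.4 to 276 FPKM and COMMD10 at 71.7 to 272 FPKM were listed at 0. The library had 368 enriched genes, 234 of them (63.6%) listed at 0 elsewhere, and 84 depleted genes. Without the brain-labelled library in the reference the enriched genes numbered 573.

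In the limb-labelled library the interferon-induced gene IFI27 stood at 1784 FPKM, against 25.3 FPKM in the brain-labelled library and 0 in the other 3, a ratio of 70.6 to the brain-labelled value. The chemokine-like protein RARRES2 (chemerin) was at 149 FPKM, the developmental regulator ZIC4 at 88.5 FPKM, the histone gene H4C3 at 86.1 FPKM, the ganglioside synthase ST8SIA1 at 85.4 FPKM, the immune GTPase GIMAP4 at 69.9 FPKM, TTC8 (cilium assembly) at 69.4 FPKM, PPCS (coenzyme A synthesis) at 67.2 FPKM and the adaptor LAT2 at 60.2 FPKM, all listed at 0 elsewhere. Of the 15 named genes, 2 were small RNAs. TIMM17B, a subunit of the mitochondrial import machinery, at 309 to 529 FPKM in the other 4, the mitochondrial ribosomal protein MRPS18C at 220 to 899 FPKM, the dUTPase DUT at 204 to 1839 FPKM, UQCRC2 at 171 to 265 FPKM and SYNJ2BP at 128 to 251 FPKM were listed at 0. The library had 314 enriched genes, 167 of them (53.2%) listed at 0 elsewhere, and 238 depleted genes. In all 5 libraries most enriched genes were low, with a median between 21.4 FPKM in the heart-labelled and 37.3 FPKM in the skin-labelled library, where few reads stand behind a value.

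**Figure D2:**
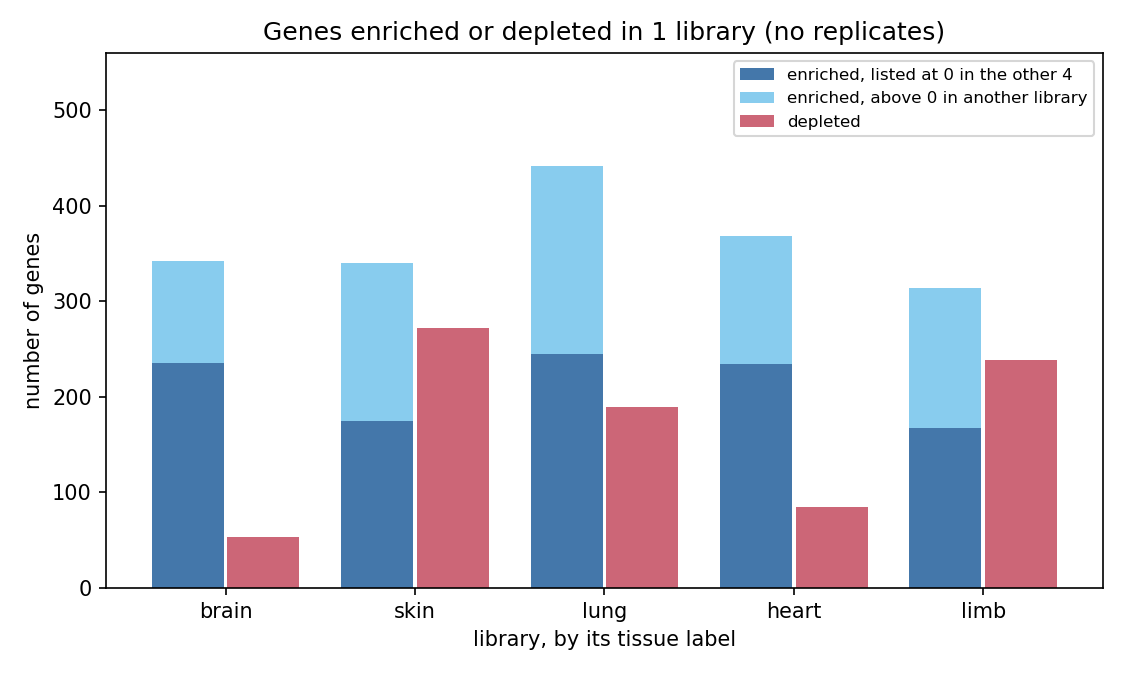
Number of genes enriched in each library (blue, split by whether the gene was listed at 0 in the other 4) and depleted in it (red). Enriched genes ranged from 314 in the limb-labelled to 442 in the lung-labelled library, and between 51.2% and 68.7% of them were listed at 0 in the other 4.

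Gene lists for cell types and processes were compared between each library and the other 4 by the median difference in log2(FPKM + 1) of their members, set against 10000 random lists matched on mean level. A percentile could be given for 18 lists in 5 libraries, 90 values in all. Of these, 20 lay outside the central 95% of the random lists, 13 above and 7 below, where 4.5 would be expected by chance. The 90 values are not independent, since each library is set against the other 4 and the genes of a list can move together. The contrast of 20 with 4.5 is therefore no test. The percentile describes these libraries and is not a test of the tissues.

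The proliferation list, of replication and mitosis genes, stood apart in all 5 libraries, high in the skin- and lung-labelled ones and low in the rest. Each library was set against the other 4, so the low values in part follow from the high ones. A reference without both the skin- and lung-labelled libraries was not run. The ubiquitin-conjugating enzyme UBE2C of the anaphase-promoting complex stood at 372 FPKM in the skin-labelled and 290.2 FPKM in the lung-labelled library, against 1.13 FPKM in the brain-labelled library and 0 in the other 2. The mitotic cyclin CCNB1 was at 123 and 284 FPKM in the skin- and lung-labelled libraries and BIRC5 (survivin) at 227 and 102 FPKM, both listed at 0 in the other 3. The replication clamp PCNA was at 318 FPKM in the lung-labelled, 99.8 FPKM in the skin-labelled, 76.1 FPKM in the limb-labelled and 34.8 FPKM in the heart-labelled library and listed at 0 in the brain-labelled one. The median difference over the 17 measured members was 4.22 in the lung-labelled library, above all of the 10000 random lists, with 16 of 17 members higher than the mean of the others, and 2.94 in the skin-labelled library (percentile 99.99, 12 of 17 higher). It was -2.06 in the brain-labelled library (below all random lists), -1.94 in the heart-labelled (percentile 0.02) and -2.06 in the limb-labelled library (percentile 0.85). The members were not uniform. In the skin-labelled library the replication helicase subunits MCM4, MCM5 and MCM7 and the mitotic kinase AURKB were listed at 0 and RRM2 at 0.45 FPKM, and in the lung-labelled library the cyclin CCNA2 was listed at 0, against 70.7 FPKM in the skin-labelled one. AURKB was highest in the brain-labelled library, at 39.1 FPKM, and MCM4 in the heart-labelled library, at 17.2 FPKM. Without the lung-labelled library in the reference the brain-labelled value was -1.30 (percentile 1.39) and the heart-labelled value -1.27 (percentile 2.37). The limb-labelled value then fell inside the central range (-1.27, percentile 29.7), as it did without the skin-labelled library (-1.89, percentile 12.6) and with the median of the others as reference (-1.68, percentile 3.38).

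Matrix and contractile genes stood apart in the heart-, limb- and lung-labelled libraries. SPARC, a collagen-binding matrix protein, stood at 5472 FPKM in the heart-labelled and 855 FPKM in the lung-labelled library, and the collagen chain COL1A2 at 523 FPKM in the heart-labelled, 311 FPKM in the brain-labelled, 174 FPKM in the limb-labelled, 19.7 FPKM in the skin-labelled and 6.0 FPKM in the lung-labelled library. Fibronectin (FN1) was at 262 and 20.9 FPKM in the heart- and lung-labelled libraries. The median difference of the fibroblast and matrix list was 2.43 in the heart-labelled library (percentile 99.99), where all 10 measured members were higher than the mean of the others, and -1.49 in the lung-labelled library (percentile 1.5), where 9 of 10 were lower. Smooth muscle actin ACTA2 was at 9827 FPKM in the limb-labelled, 8209 FPKM in the heart-labelled, 4650 FPKM in the brain-labelled, 3067 FPKM in the skin-labelled and 589 FPKM in the lung-labelled library, and calponin (CNN1) at 601 FPKM in the limb-labelled and 22.8 FPKM in the lung-labelled library. The median of the 5 measured smooth muscle and pericyte genes was 1.62 in the heart-labelled (percentile 98.8), 1.61 in the limb-labelled (percentile 99.2) and -2.53 in the lung-labelled library (percentile 0.565). Without the skin-labelled library in the reference the heart-labelled value (1.08, percentile 96.1) and the limb-labelled value (0.85, percentile 94.3) fell inside the central range, as did the limb-labelled value without the lung-labelled library (1.01, percentile 96.3) and, narrowly, with a pseudocount of 5 (0.90).

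Interferon-induced genes stood apart in 3 libraries. IFI6, an interferon-induced mitochondrial protein, was at 4758 FPKM in the limb-labelled and 2296 FPKM in the brain-labelled library. It was at 1538 FPKM in the heart-labelled, 411 FPKM in the skin-labelled and 362 FPKM in the lung-labelled library. The antiviral GTPase MX1 was at 487 FPKM in the brain-labelled and 29.1 FPKM in the skin-labelled library, and the ubiquitin-like protein ISG15 at 333 FPKM in the brain-labelled, 47.3 FPKM in the lung-labelled and 9.77 FPKM in the heart-labelled library and at 0 in the other 2. USP18, which removes ISG15 from proteins, was at 519 FPKM in the limb-labelled and 365 FPKM in the brain-labelled library. The list median was 2.61 in the brain-labelled library (percentile 99.98), with 9 of 9 measured members higher than the mean of the others, 2.16 in the limb-labelled library (percentile 99.9, 6 of 9 higher) and -2.52 in the skin-labelled library (percentile 0.155, 8 of 9 lower). Without the skin-labelled library in the reference the limb-labelled median was 1.30 (percentile 99.1). The lung-labelled (0.18, percentile 48.4) and heart-labelled (-0.21) medians lay within the random range.

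**Figure D3:**
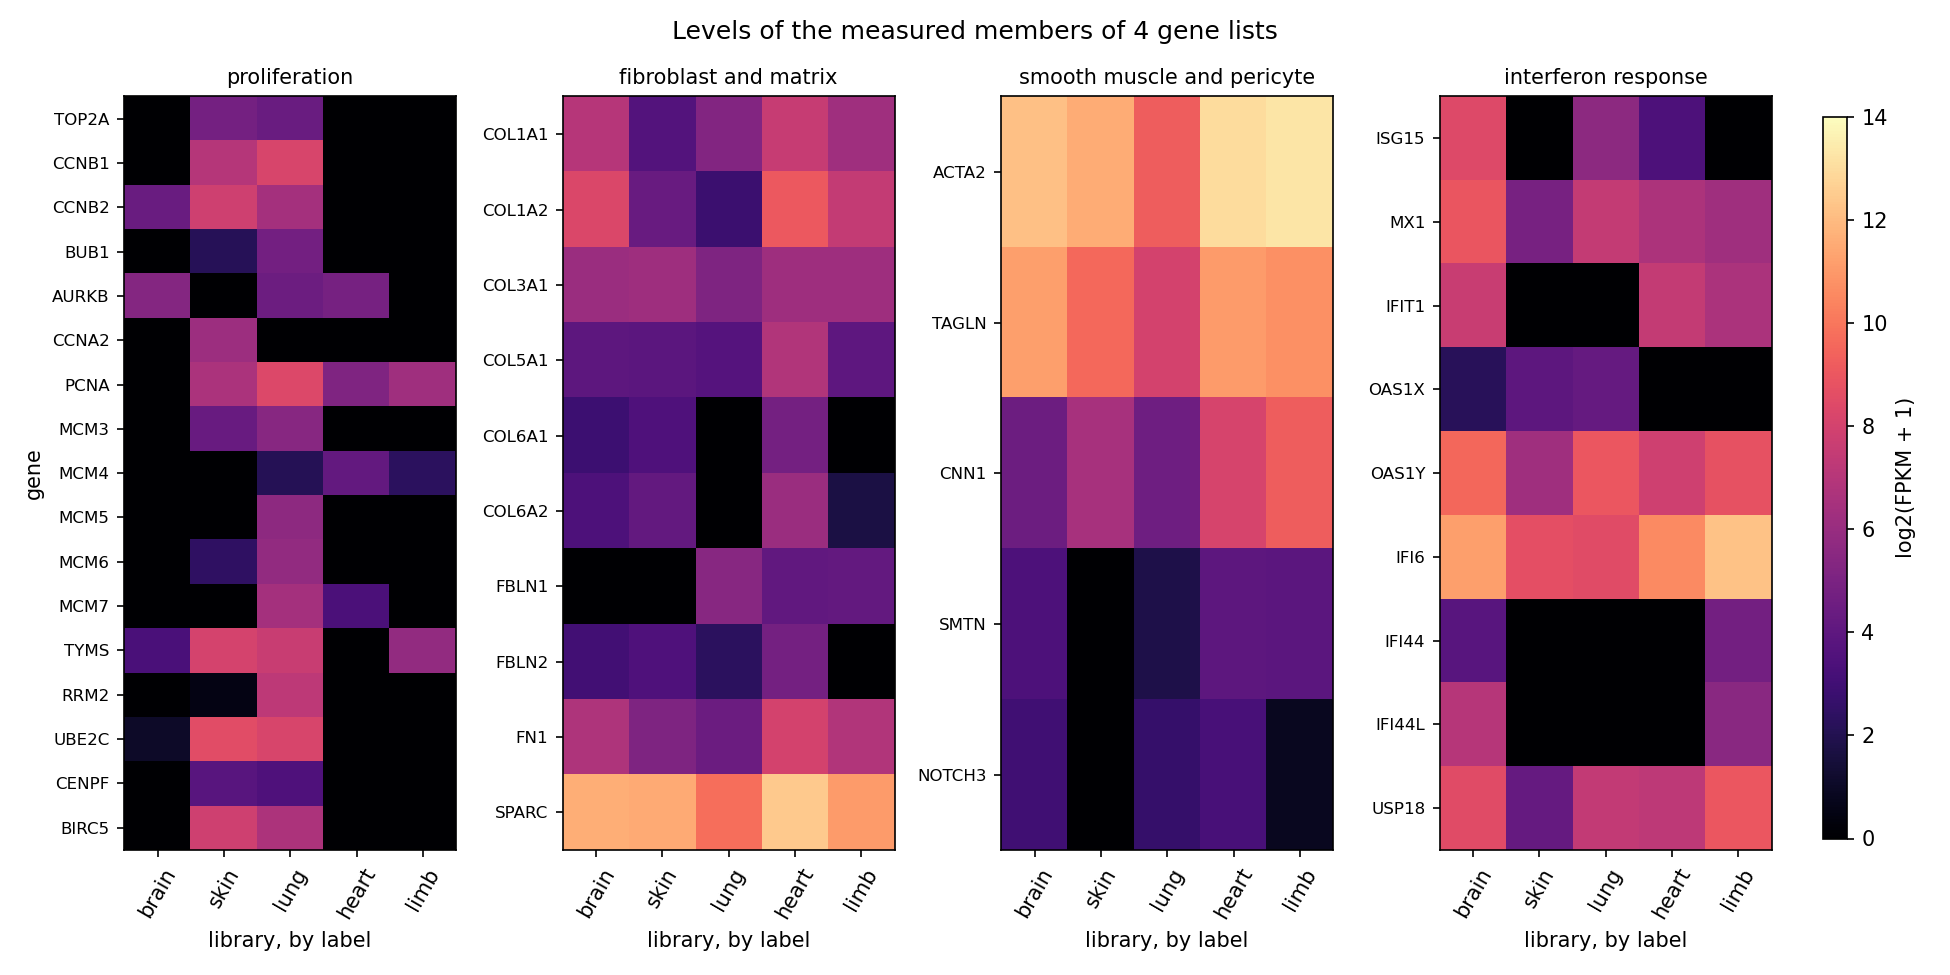
Levels of the measured members of 4 gene lists as log2(FPKM + 1), with genes as horizontal bands and libraries, named by label, as columns, where black is 0. UBE2C, CCNB1 and BIRC5 stand out in the skin- and lung-labelled columns, SPARC is highest in the heart-labelled column at 5472 FPKM, and all 9 interferon genes are above 0 in the brain-labelled column.

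Stress and metabolic genes stood apart in the lung-, skin- and limb-labelled libraries. The chaperonin cofactor HSPE1 was at 2879 FPKM in the lung-labelled library and 937 to 1474 FPKM in the others, and HSPA8 at 1465 FPKM against 531 to 1106 FPKM. All 8 heat shock genes were higher in the lung-labelled library than the mean of the others, with a median of 1.30 (percentile 99.6). Oxidative phosphorylation genes had a median of 0.63 in the skin-labelled library (percentile 98.2, 14 of 17 higher), led by COX7A1, at 710.0 FPKM there and 8.19 FPKM in the lung-labelled library. Glycolytic genes had a median of -0.55 in the limb-labelled library (percentile 1.69, 11 of 14 lower), where GPI was at 1.39 FPKM against 37.6 to 219.5 FPKM in the other 4. These last values fell inside the central range without the brain-labelled (0.57 and -0.39) or the lung-labelled library (0.54 and -0.38), the skin-labelled one also without the limb-labelled library (0.52) and the limb-labelled one without the heart-labelled library (-0.44). Both also fell inside it with the median of the others as reference (0.49, percentile 95.3, and -0.33, percentile 12.6). Fatty acid oxidation genes were nearest to the limit in the heart-labelled library (2.13, percentile 97.4) and immediate early genes in the heart-labelled library (-0.85, percentile 9.15), and neither list left the central range in any library.

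Short lists gave the remaining values outside the central range. The skeletal muscle list, with 3 measured members, had a median of 4.26 in the limb-labelled library (percentile 99.7), resting on ACTA1 and TNNT1, and fell inside the central range with a pseudocount of 0.1 (percentile 96.5). The limb patterning list, also with 3, had a median of 4.47 in the brain-labelled library (percentile 99.4), resting on the homeobox genes MSX1 at 31.6 FPKM and MSX2 at 33.4 FPKM, with the third member, PRRX1, listed at 0. It fell inside the central range when members with a mean down to 0.1 FPKM were taken in (2.10, percentile 97.4). The cartilage and bone list, with 4, had a median of 2.66 in the heart-labelled library (percentile 98.7), where SPP1 was joined by the regulators SOX9 at 14.04 FPKM and RUNX2 at 10.7 FPKM. This value fell inside the central range without the skin-labelled (1.77, percentile 92.9) or the lung-labelled library (2.31, percentile 96.5), with a pseudocount of 5 (1.30, percentile 95.2) and with members at a mean of 5 FPKM or more (1.87, percentile 91.0). In the limb-labelled library, whose label matches the list, the median was 2.12 (percentile 96.8, 3 of 4 higher), just inside the central range. RUNX2, at 29.2 FPKM, and SPP1 were highest there. The fetal growth list, with 4, had a median of 3.45 in the skin-labelled library (percentile 99.3), where the RNA-binding proteins IGF2BP2 and IGF2BP3 were at 24.0 and 10.6 FPKM and the imprinted gene PEG10 at 12.7 FPKM, while IGF2 itself was listed only in the limb-labelled library, at 30.6 FPKM. The keratinocyte list in the skin-labelled library (0.18, percentile 62.8) and the alveolar list in the lung-labelled library (-1.10, percentile 6.04) stayed within the random range, as did the neural progenitor and astrocyte, oligodendrocyte and airway lists in all 5 libraries. The neuron and cardiomyocyte lists had 2 measured members each and were given no percentile.

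The 10 pairs of libraries were compared gene by gene. The brain- and heart-labelled libraries were the most alike, with a Pearson correlation of 0.668 across 8694 genes on the log2(FPKM + 1) scale and a Spearman correlation of 0.618. Between them 2132 genes differed by the fixed rule of size, 1113 higher in the brain-labelled and 1019 in the heart-labelled library. The brain- and limb-labelled (Pearson 0.638, 2553 genes) and the heart- and limb-labelled libraries (0.633, 2552 genes) came next. Pairs of the skin-labelled library with the brain-labelled (0.610, 2764 genes), lung-labelled (0.601, 2825 genes), heart-labelled (0.596, 2834 genes) and limb-labelled library (0.578, 2826 genes) were lower, as were the lung-labelled library with the brain-labelled (0.607, 2700 genes) and the heart-labelled library (0.579, 2814 genes). The lung- and limb-labelled libraries had the lowest Pearson correlation, 0.561, and 2972 differing genes, 1691 higher in the lung-labelled and 1281 in the limb-labelled library. Among them were UBE2C and RRM2, listed at 0 in the limb-labelled library, and ACTA2, at 589 against 9827 FPKM. Genes are not independent replicates, so these correlations carry no p-value, and the differing counts also move with the number of genes that each library listed above 0.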

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

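The minimum of 200 FPKM, the limit to genes other than small RNAs and the median as list reference were chosen after the data were seen. Counts of genes moved with the rule. With a minimum of 1 FPKM, enriched genes numbered 523 in the brain-labelled and 625 in the heart-labelled library. With 50 FPKM they fell to 60 (brain label), 132 (skin), 129 (lung), 55 (heart) and 83 (limb), and with 200 FPKM to 14, 18, 13, 10 and 5 in that order. The library with the most enriched genes was lung-labelled at 10 FPKM, heart-labelled at 1 FPKM and skin-labelled at 50 and 200 FPKM. A ratio of 2 gave 603, 687, 818, 585 and 590, and the mean of the other 4 as reference 695, 759, 896, 696 and 675. A pseudocount of 5 gave 214 in the heart-labelled and 207 in the limb-labelled library. Leaving out 1 library from the reference moved 3 counts by over 1.5 times: 555 for the brain label without the heart-labelled library, 573 for the heart label without the brain-labelled one and 517 for the skin label without the lung-labelled one. Lower minimums and ratios, and fewer libraries in the reference, admit more genes by construction.

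Depleted genes with a minimum of 1 FPKM numbered 88 (brain label), 411 (skin), 132 (heart) and 373 (limb). With 50 FPKM they numbered 11, 63, 44, 21 and 37 in the order brain, skin, lung, heart and limb, and with a ratio of 2 there were 94 (brain), 299 (lung) and 188 (heart).

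Between pairs, a minimum of 1 FPKM gave 3206 differing genes for the brain- and heart-labelled libraries. With 50 FPKM the brain-labelled library differed from the skin-, lung-, heart- and limb-labelled ones in 957, 866, 513 and 735 genes, the skin-labelled from the lung-, heart- and limb-labelled in 1049, 976 and 1146, the lung-labelled from the heart- and limb-labelled in 929 and 1087, and the heart-labelled from the limb-labelled in 697. With 200 FPKM the same pairs gave 189, 163, 80, 93, 147, 192, 189, 196, 186 and 103. The pair of the brain- and heart-labelled libraries had the highest Pearson correlation in the main setting and the 4 alternatives, while the lowest moved from the lung- and limb-labelled pair to the skin- and limb-labelled one (0.47) among genes with a mean of 10 FPKM or more. The values themselves moved in 39 of 40 alternatives, the highest going from 0.668 to 0.546 with a pseudocount of 0.1 and 0.773 with one of 5. Genes detected kept within 1.5 times at limits of 0.1 and 5 FPKM.

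Alternatives were run for the 20 list medians outside the central 95% and for the keratinocyte and alveolar lists. Of 239 alternative values, 217 stayed on the same side of the central 95% and none of the medians took the opposite sign, though the keratinocyte median in the skin-labelled library went from 0.18 to 0 without the lung-labelled library and with the median of the others as reference. The skeletal muscle list in the limb-labelled library fell inside it with a pseudocount of 0.1 (6.60), and the alveolar list in the lung-labelled library left it with a pseudocount of 5 (-0.54). The cause was not tested. The other 20 that fell inside it belonged to cartilage and bone in the heart-labelled library (4), glycolysis in the limb-labelled (4), oxidative phosphorylation in the skin-labelled (4), proliferation in the limb-labelled (3), smooth muscle in the limb-labelled (3) and heart-labelled (1) and limb patterning in the brain-labelled library (1). With members at a mean of 5 FPKM or more, the alveolar, skeletal muscle and fetal growth lists had too few members to give a value. Thinning to equal depth was not run, since no counts were analysed. Depth limits what a 0 means in each library.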

Other observations

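The tests on the markers, on mixing, on cells of 1 kind, on depth, on few cells and on the genes listed in the skin-labelled library were chosen after their results were seen, and so were all genes named here outside the fixed lists. The tests on the 4 lists of replication, amino acid, YAP and antigen presentation genes were written before those members were looked at, but after related genes had been seen. Leaving out each member in turn was added after their percentiles were known.

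Eye and forebrain regulators were listed in libraries of all 5 labels. SIX3, a regulator of eye and forebrain development, was at 10.6 to 54.0 FPKM in all 5 libraries, as PAX6 was, and MAB21L1, which acts in lens and eye formation, at 195 FPKM in the lung-labelled, 67.4 FPKM in the skin-labelled and 4.55 FPKM in the brain-labelled library. Of 12 further eye field and lens regulators, between 1 and 3 were above 0 in each library, and of 17 lens structural proteins 1 or 2. MEIS1 was above 0 in all 5 libraries, at 0.45 to 109 FPKM. SIX6 and OTX2 were listed at 0 in all 5, and RAX was listed only in the heart-labelled library, at 2.37 FPKM. Neither list left the central range in any library, the highest percentile being 96.4 for the regulators in the lung-labelled one, with 3 measured members. The small heat shock protein CRYAB, a lens protein also found in muscle and stressed cells, was above 0 in all 5 libraries, at 3143 FPKM in the skin-labelled and 455 to 809 FPKM in the others, while CRYAA was listed at 0. The intermediate filament VIM was at 1011 to 2251 FPKM. ALDH1A1, which makes retinoic acid, was at 3075 FPKM in the limb-labelled, 317 FPKM in the skin-labelled and 268 FPKM in the brain-labelled library, against 2.34 FPKM in the lung-labelled and 0 in the heart-labelled one.

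The next genes were picked singly by their values. CCN2, a matricellular growth factor, was at 1010 FPKM in the limb-labelled, 630 FPKM in the heart-labelled and 307 FPKM in the brain-labelled library, against 7.97 and 0.63 FPKM in the skin- and lung-labelled ones. ANKRD1, a cardiac ankyrin repeat protein that YAP also induces, was at 1308, 765 and 850 FPKM in the first 3 and at 20.7 FPKM and 0 in the last 2. IL6 was listed only in the heart-labelled and limb-labelled libraries, at 147 and 165 FPKM. The neutrophil chemokine CXCL5 was at 763 FPKM in the skin-labelled and 449 FPKM in the limb-labelled library, against 3.36 FPKM in the lung-labelled one.

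The absence of the labelled tissues' markers, together with abundant genes in common, was the first pattern weighed. An exchange of labels among the 5 libraries is argued against, since no library listed more than 16.7% of any of the 5 main tissue lists, unless the markers lay below the level of a read. Near-complete mixing of material or barcodes is argued against by 124 named genes at 200 FPKM or more in a library and at 0 in another, with 24 to 53 such zeros in each library, though mixing of a small share stays open. Of 1229 named genes at 200 FPKM or more in a library, 24 to 53 were at 0 in each library. Low depth is therefore argued against as the reason for missing a whole set of markers at such levels, though single genes can be missed. For markers at lower levels it cannot be told apart from true absence. The table holds no tissue to show at which level the markers would lie. In the brain-labelled library 1 read was worth roughly 7.20 FPKM. That level can be too high and rests in part on genes that lie on the spacing by chance. That the libraries may hold 1 kind of cell also stays open: PAX6 and SIX3 were above 0 in all 5 libraries, but so were 32.5% of the 1075 named genes with a mean of 20 to 40 FPKM.

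The proliferation genes of the skin- and lung-labelled libraries were the second pattern. Depth would move genes of like level together, yet the list stood at the percentiles 99.99 and 100 of matched random lists. These percentiles are also what picked out the pattern, so they are no separate evidence against depth. The skin- and lung-labelled libraries had 77.0% and 90.3% as many genes at 1 FPKM or more as the brain-labelled one. A list of other replication and chromatin genes, with H2AZ1 at 2170 and 2072 FPKM against 308 to 466 FPKM in the other 3 libraries, lay at percentile 99.98 in the skin-labelled and 100 in the lung-labelled library, in line with the hypothesis that these libraries held more dividing cells. Whether that reflects the tissues or the phase of a few captured cells cannot be told apart, since the number of cells is not given and 13 of the 17 members were listed at 0 in the brain-labelled library.

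The third pattern was low amino acid enzymes in the skin-labelled library, where ASNS was listed at 0, PSPH (serine synthesis) at 7.38 FPKM and the tryptophanyl-tRNA synthetase WARS1 at 0.49 FPKM, against 145 to 730 FPKM for the 3 genes in the other 4 libraries. A further such enzyme seen with them, TARS1, was lowest in the lung-labelled library, at 0.62 FPKM. It was at 20.2 FPKM in the skin-labelled library and at 176 to 293 FPKM in the limb-, heart- and brain-labelled ones. In 18 other genes of the amino acid response driven by ATF4, such as PSAT1 (0 against 74.2 to 226 FPKM) and ATF4 itself (170 against 299 to 1148 FPKM), the median was -2.10 in the skin-labelled library, at percentile 0.04, as a weaker amino acid response predicted, with 16 of 18 lower than the mean of the others and DDIT3 and AARS1 higher. The same list was high in the heart-labelled (1.17, percentile 99.3) and limb-labelled (0.85, percentile 97.7) libraries and lay at -0.64 (percentile 3.17) in the lung-labelled and 1.04 (percentile 96.0) in the brain-labelled one. The smaller number of genes listed in that library is argued against as the whole cause, since 44.4% of the 18 were at 0 where 95% of matched random lists had 5.56% to 33.3%. A weaker response in that library stays a hypothesis, and a difference between tissues is untested with 1 library each.

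A pair of further hypotheses was tested. A stronger YAP and serum response in the limb-labelled library was proposed from CCN2 and ANKRD1. The median of 15 other targets was 0.56 at percentile 88.5, with 11 of 15 higher than the mean of the others. By the rule written before these members were looked at, that percentile counts against the hypothesis. The limb-labelled percentile ran from 85.8 to 92.1 when each target was left out in turn, a check added later. The outcome therefore lies near the limit of the rule. The comparison cannot decide on a response shared with the heart- and brain-labelled libraries, where CCN2 and ANKRD1 were also high. The list median was 0.47 (percentile 71.8) in the heart-labelled and 0.55 (percentile 67.9) in the brain-labelled library. It was -1.03 (percentile 10.6) in the skin-labelled and -1.06 (percentile 2.745) in the lung-labelled library, all inside the central range. Antigen presentation genes did not stand apart with the interferon genes in the brain-labelled library, with a median of 0.21 at percentile 59.5 over 10 genes (36.9 to 77.5 when each was left out in turn).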
